A study of Mus musculus with 52 samples.

How the data were processed

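The series profiles the suprachiasmatic nucleus (SCN), the paired nuclei of the hypothalamus that hold the circadian pacemaker, from male mice kept in darkness or given light during the subjective night. It holds bulk RNA-seq, ChIP-seq of acetylated and trimethylated histone H3, and single-nucleus RNA-seq. The bulk RNA-seq is made of a light-pulse experiment with 16 libraries and an Npas4 experiment with 12 libraries. Of the 52 samples given, the 18 single-nucleus samples are not analysed here, and the ChIP input samples are not used here because no peak list belongs to them. Circadian time (CT) counts hours of the animal's own cycle in constant darkness.

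Per the labels' protocols, mRNA was purified from SCN tissue with a Dynabead kit and libraries followed the TruSeq procedure. Each bulk library pooled 6 pairs of SCN, per the series' design text, and each ChIP sample 2 pairs. A library is therefore a pool of animals. Nothing in the sources used here says whether the libraries of a group come from separate days, so p-values measure the spread between these libraries, which may in part be technical.

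The authors deposited whole-number read counts per gene symbol, not normalised, for 21999 genes in each experiment. They also deposited RPKM values of the same libraries. Dividing the deposited counts by the whole gene length and the library total gave the deposited RPKM with a largest relative departure of 1e-09. Per the submitters' processing notes, STAR 2.7.1a, STAR 2.5.2b, HTSeq 0.9.1, featureCounts 1.6.2, BWA 0.7.16a, SAMtools, MACS2 2.1.1, HOMER 4.9.1, bedtools 2.25.0 and the mouse genome build mm10 were used in the series. Which tool made which file, the counting options and the use of strand are not given in the sources used here. Genes that overlap, or that share reads with a near-identical copy, are uncertain for that reason. Each row of the count tables names a gene, and every column belongs to 1 of the 28 libraries.

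The authors deposited 1 peak list per histone mark and lighting condition, in narrowPeak form. Each peak has a position, a linear fold enrichment over the background and a -log10 q-value given by the authors' peak caller. Every deposited peak has a -log10 q-value of 2 or more. With 1 library per list there are no replicates, so the peak comparisons describe these libraries.

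Counts were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F-test after TMM scaling and the filterByExpr filter. This left 14524 genes in the light-pulse experiment and 15001 in the Npas4 experiment. P-values were adjusted by the Benjamini-Hochberg method over all genes tested in a comparison, and a gene was called at an adjusted p of 0.05. Each experiment was fitted as a whole, so that its groups share 1 estimate of the spread. CPM values are counts relative to the TMM-scaled library total, given as mean ± SD over libraries, and log2 fold changes as estimate ± SE. The light-pulse model held the sequencing batch of the labels as a term, and the model of the Npas4 experiment held the 4 groups alone. Light of 0.5 h, 1 h and 3 h was compared with dark at CT17, and light of 6 h with dark at CT23. The comparison of 1 h with 0.5 h and that of 3 h with 1 h were added after seeing the data.

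In the light-pulse experiment, libraries with the same number and with or without the suffix s differed by a chi-square of 10.4 to 30.3 per degree of freedom, where 1.5 or less would have marked a repeat, and were kept apart. This check finds a library sequenced again, but not 2 libraries made from the same pool of SCN. The 4 libraries at CT17 and at 0.5 h may therefore hold fewer independent pools, which leaves their SD and p-values uncertain. With libraries of a number summed and no batch term, 55 genes were called at 0.5 h, against 64 in the main fit. On the first principal component the 4 libraries with the suffix s lay above all others, whereas the other libraries of label batch 2 lay at the opposite end, partly overlapping label batch 1. A fit with a term for the suffix in place of the batch of the labels was therefore added after seeing the data, and a selection of its values stands beside the main ones. The use of gene ends in place of start sites for peaks, a matched background for the suffix-term list of induced genes and the explanations weighed in the closing observations were also chosen after seeing the data, as far as stated there. The other choices, including the tests, the gene lists and the alternatives, were made before the data were examined.

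Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, in limma 3.58.1. The 22 lists were immediate-early genes, core clock genes, SCN peptides and receptors, SCN identity transcription factors, MAPK and cAMP feedback genes, late-response neuronal genes, NPAS4 targets named in other neurons, ion channels, GABA synapse genes, glutamate receptor genes, cytosolic heat shock genes, cold-inducible RNA-binding genes, ER chaperone genes, cholesterol synthesis genes, and markers of astrocytes, oligodendrocytes, microglia, endothelial and mural cells, ependymal cells and tanycytes, meningeal fibroblasts, choroid plexus and neighbouring hypothalamic neurons. Each experiment had 110 list tests, adjusted together. In the light-pulse experiment 45 tests passed with the preset correlation, 16 with an estimated correlation and 26 with fry, and in the Npas4 experiment 39, 15 and 19. The list p-values printed with the results are adjusted values with an estimated correlation unless fry is named. Several genes are members of more than 1 list.

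Genes named in the text followed a fixed rule. It took Npas4 in every comparison, and the 10 largest rises and 10 largest falls past the threshold with a mean log2 CPM of 1 or more and no overlap between the libraries of the groups. It also took from each list up to 4 members with the smallest p, the most abundant cell type markers, and Per1, Per2, Vip, Grp and Avp throughout. Fos in the null after light was named after its values were seen, since its response differed between genotypes. Predicted and unnamed loci were counted and not named. Some genes that met the rule are not reported here.

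Replicate numbers were checked for pairing in the Npas4 experiment, by correlating the deviations of libraries from their group means. Between wild-type light and dark, the lowest correlation of a same-number pair was 0.222, between null light and dark 0.369, and between null and wild type in the dark 0.451. These numbers therefore pair the libraries, and the fit with the replicate number as a block is given beside those results where it changed a call or a count. Between null and wild type in light 2 of 3 same-number pairs exceeded 0.1, with a median of 0.29 and a lowest value of 0.0197. Over all 18 same-number pairs 17 exceeded 0.1, with a median of 0.452. Not every pair exceeded 0.1, so the block is not used for these, although most of these pairs correlated. In the light-pulse experiment 32 of 52 same-number pairs exceeded 0.1. The counts under the block had been seen before this criterion was applied.

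Peak lists were compared with bedtools 2.31.1 at a minimum overlap of 1 bp. Gene positions came from the RefSeq annotation of GRCm38.p6, the same build as mm10, and 14432 of the 14524 genes tested at 1 h had one (99.4%). The annotation table gives no strand, so that transcription start sites could not be placed and both annotated ends of a gene were used. Proximity within 10 kb of either end was tested with a two-sided Fisher exact test in SciPy 1.17.1, and figures were drawn with matplotlib 3.10.9.

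Alternatives were RLE size factors, DESeq2 1.42.0, other low-count filters, limma-trend on log2 of the deposited RPKM plus a pseudocount of 1, other covariates and sample sets, other controls, a stricter fold threshold and leaving out each library in turn. The model was tested on simulated counts with 200 changed genes in 7 runs. At 0.5 h it recovered 98.3% of 2-fold changes with 4.5% false calls on average, at 1 h 93.3% with 5.5%, for wild-type light 97.0% with 5.33%, and for the difference of responses 88.9% with 4.85%. Of 4-fold changes it recovered 99.7%, 98.7%, 100% and 99.0% in the same order. The simulated counts held no differences between batches, with the suffix s or between replicate numbers. These rates therefore do not cover how the calls at 1 h and 3 h depend on the batch term. Nor do they cover the correlation of replicate numbers in the Npas4 experiment. In the real difference of responses Fos and Nr4a1 passed. Larger than 2-fold estimates for Dusp4 (-1.29 in log2, adjusted p = 0.201) and Fosl2 (-1.37, adjusted p = 0.921) did not. The simulated recovery is thus no measure of how many such differences the real test would find.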

Results

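Bulk RNA-seq of the SCN measured how light in the subjective night, when light shifts the clock, changes gene expression, and how these responses differ in mice without Npas4. Npas4 encodes a bHLH-PAS transcription factor that is induced by neuronal activity. In the light-pulse experiment mice stayed in the dark until CT17 (4 libraries) or CT23 (2 libraries), or received light for 0.5 h (4 libraries), 1 h, 3 h or 6 h (2 libraries each) from CT17. In the Npas4 experiment, null mice and wild-type littermates were kept in the dark or received 1 h of light, with 3 libraries in each of the 4 groups. H3K27ac, a mark of active promoters and enhancers, and H3K4me3, a mark of active promoters, were profiled by ChIP-seq in dark and light with 1 peak list each.

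The 12 light-pulse libraries without the suffix s held 12477382 to 15369985 counted reads each and the 4 with it 27413860 to 30149286. The 12 libraries of the Npas4 experiment held 26638939 to 32097975. The first principal component of the light-pulse libraries carried 33.9% of the variance. On it the 4 libraries with the suffix s lay between 15.4 and 25.2, the 7 other libraries of label batch 2 between -16.2 and -6.13, and the 5 libraries of label batch 1 between -6.61 and 8.64. All libraries of 1 h, 3 h and 6 h belong to label batch 2, so that within label batch 1 these times have no library to compare.

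**Figure D1:**
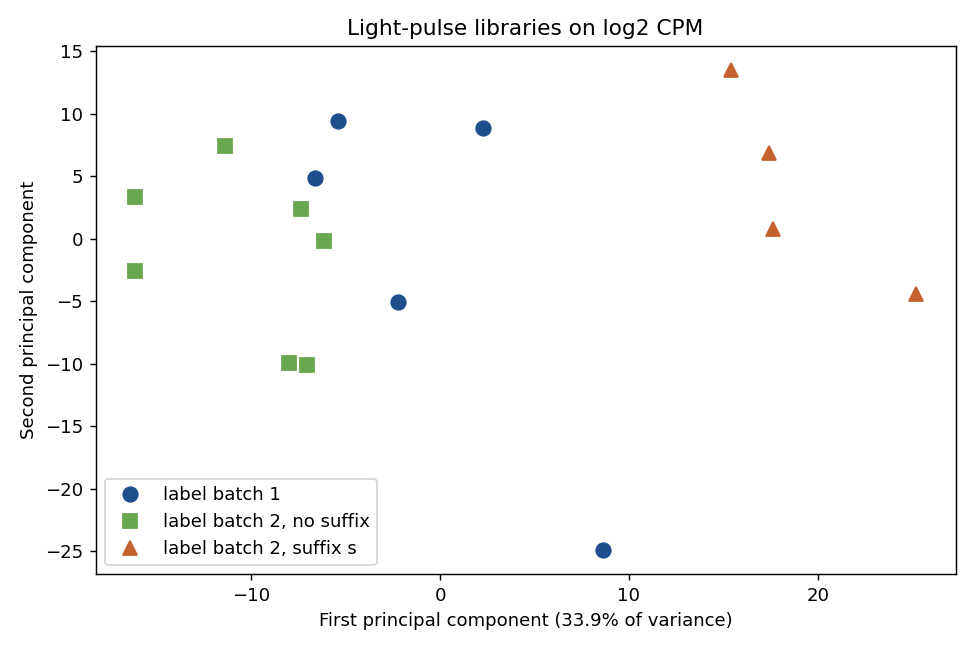
Scores of the 16 light-pulse libraries on the first and second principal components of log2 CPM, in arbitrary units, with 1 point per library, circles for label batch 1, squares for label batch 2 without the suffix s and triangles for the suffix s. The 4 triangles lie at 15.4 or more on the first component, to the right of all circles and squares.

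The first comparison asks what the SCN expresses after 0.5 h of light. Immediate-early genes rose most. The AP-1 subunit Fosb rose by 6.40 ± 0.16 in log2, from 1.29 ± 0.559 to 116 ± 24.7 CPM (SD, n = 4 each; adjusted p = 2.1e-12), and Fos rose by 4.96 ± 0.12, from 6.83 ± 0.856 to 215 ± 11.5 CPM. The zinc-finger factor Egr1 rose by 5.03 ± 0.15 to 520 ± 71.8 CPM, with Egr2 up by 6.09 ± 0.21 and the AP-1 subunit Junb by 4.46 ± 0.12. Npas4 rose by 2.13 ± 0.13, from 10.7 ± 1.01 to 47.4 ± 4.25 CPM (adjusted p = 7.83e-08), and the nuclear receptor Nr4a1 by 3.72 ± 0.10. The clock repressor gene Per1 rose by 0.87 ± 0.07, from 53.2 ± 4.43 to 97.2 ± 7.98 CPM (adjusted p = 2.81e-06), whereas Per2 had a log2 change of 0.02 that did not pass.

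Of 31 immediate-early genes measured at 0.5 h, 24 rose and none fell, and 28 passed when adjusted over the list alone (list adjusted p = 1.41e-09). Among 24 MAPK and cAMP feedback genes 7 rose and 1 fell, with 13 past when adjusted over the list alone, 12 of them higher (list adjusted p = 6.22e-05). Their rises included Rrad and Gem, small GTPases that limit calcium channels, by 2.1 ± 0.14 and 1.40 ± 0.11. Rasd1, a Ras-like G protein of the SCN, fell by 0.46 (adjusted p = 0.00629). Of 29 late-response genes 5 rose, among them the kinase gene Plk2 by 0.83 ± 0.06, and 11 passed when adjusted over the list alone. Of 13 NPAS4 targets 4 rose, 7 when adjusted over the list alone, and each of these lists had a list adjusted p of 3.74e-05. Of 23 core clock genes 2 rose, Per1 and Bhlhe40 (by 0.38 ± 0.04), and 3 passed when adjusted over the list alone, 2 of them higher, with a list adjusted p of 0.758. None of 21 SCN peptides and receptors passed, 1 when adjusted over the list alone (list adjusted p = 0.871). Log2 changes were -0.25 for Vip, -0.12 for Avp and 0.08 for Grp, all with an adjusted p of 1.

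None of 8 meningeal fibroblast markers passed, with a list median of 1.54 (list adjusted p = 0.486). In all, 64 genes differed after 0.5 h, 62 higher and 2 lower, and the lower genes were Rasd1 and Cited2, a partner of CBP and p300, which fell by 0.29 (adjusted p = 0.016). All 64 were also called with the suffix term, which called 68.

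The second comparison addresses 1 h of light. AP-1, Egr and Nr4a genes were still high: Fosb lay 6.14 ± 0.18 above the dark in log2, Egr1 4.78 ± 0.16 and Nr4a1 3.75 ± 0.12. The AP-1 subunit Fosl2 rose by 4.18 ± 0.13, from 10.8 ± 1.06 CPM in the dark (SD, n = 4) to 190 ± 0.904 CPM (n = 2). Prok2, a secreted output peptide of the SCN, rose by 4.42 ± 0.22, from 1.22 ± 0.537 to 16.9 ± 2.29 CPM (adjusted p = 3.9e-09), and by 3.37 with the suffix term. The postsynaptic scaffold gene Homer1 rose by 2.06 ± 0.09, from 33.2 ± 1.13 to 138 ± 6.26 CPM. Per1 rose by 1.83 ± 0.09 to 182 ± 4.06 CPM and Per2 by 0.77 ± 0.09 to 92.5 ± 15.4 CPM (adjusted p = 9.09e-05). Npas4, at 11.4 ± 2.23 CPM, had a log2 difference from the dark of 0.09 ± 0.18 (adjusted p = 0.79).

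At 1 h 24 of 31 immediate-early genes rose, 25 when adjusted over the list alone (list adjusted p = 5.24e-07), with Fos at 146 ± 3.06 CPM. Of 24 MAPK and cAMP feedback genes 15 rose, and 18 passed when adjusted over the list alone, 17 of them higher, with rises of Rrad by 3.56 ± 0.16 and the MAPK phosphatase gene Dusp4 by 2.96 ± 0.16. Of 29 late-response genes 17 rose and 2 fell, with 22 past when adjusted over the list alone, 20 of them higher (list adjusted p = 1.04e-05). They included Vgf, a neuropeptide precursor, which rose by 1.26 ± 0.14. Of 13 NPAS4 targets 7 rose and 1 fell, 8 when adjusted over the list alone (7 of them higher), and with the suffix term no late-response or NPAS4 target gene fell. The feedback and NPAS4 target lists had a list adjusted p of 3.74e-05 each. Of 23 clock genes 4 rose and 3 fell, 11 when adjusted over the list alone, 7 of them higher (list adjusted p = 0.34), and with the suffix term 4 rose and none fell. Among 21 SCN peptides and receptors 4 rose and 3 fell, 10 when adjusted over the list alone, 5 of them higher (list adjusted p = 0.492), and with the suffix term 3 rose and none fell. Npy6r, a receptor gene of the neuropeptide Y family, fell by 1.53 (adjusted p = 0.000827) and with the suffix term fell by 1.19. The log2 changes of Vip (-0.25), Grp (0.21) and Avp (-1.46, adjusted p = 0.0518) did not pass.

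Markers of other cell types moved with this group of libraries. All 10 oligodendrocyte markers fell at 1 h, 10 when adjusted over the list alone, with a list adjusted p of 0.109. Among them the myelin gene Ermn fell by 1.0. With the suffix term 0 of the 10 passed, and the adjusted p of Ermn was 0.121. Within the groups that hold both kinds of library, these 10 markers were higher with the suffix s, by a median of 0.361 in log2 (lowest 0.068). Of the cholesterol synthesis genes 6 rose, 8 when adjusted over the list alone (list adjusted p = 0.309), and with the suffix term 2. Of the cytosolic heat shock genes 5 rose, 9 when adjusted over the list alone (list adjusted p = 0.34), including Dnajb1 by 0.66 ± 0.10, and with the suffix term 1.

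The label-batch model called 1218 genes at 1 h, 638 higher and 580 lower. With the suffix term 184 were called, 161 higher and 23 lower, and 170 were called in both. The share of calls that were higher was 52.4% with the label batch and 87.5% with the suffix term. Within label batch 2 alone, where both dark libraries at CT17 carry the suffix s, 2494 genes were called, and leaving out single libraries gave 172 to 2698. Genes called with the label batch and not with the suffix term included Eomes (adjusted p = 0.614 with the suffix term), Pomc (0.138), Qrfp (0.056) and Nr5a1 (0.525), a transcription factor of the ventromedial hypothalamus.

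After 3 h of light Prok2 lay 3.96 ± 0.22 above CT17 dark in log2, at 12.2 ± 0.249 CPM (SD, n = 2; adjusted p = 6.05e-08), and 2.91 above it with the suffix term. Vgf rose by 2.13 ± 0.14, from 134 ± 32.3 to 527 ± 66.2 CPM. Per2 rose by 1.17 ± 0.09 to 122 ± 3.12 CPM (adjusted p = 1.21e-06) and Per1 by 0.70 ± 0.09 (adjusted p = 0.000353). Rora, a nuclear receptor of the clock, rose by 1.43 ± 0.11, Fbxl21, an F-box gene whose product acts on cryptochromes, by 1.5 ± 0.09, and Pde10a, a cyclic nucleotide phosphodiesterase, by 1.15 ± 0.06. Npas4 had a log2 difference of -0.40 (adjusted p = 0.177).

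Of 31 immediate-early genes 19 were still higher than in the dark at 3 h, 21 when adjusted over the list alone (list adjusted p = 0.000454), with Fosb up by 3.66 ± 0.21. Of 24 MAPK and cAMP feedback genes 15 rose and 1 fell, 21 when adjusted over the list alone, 20 of them higher (list adjusted p = 3.74e-05). Of 29 late-response genes 13 rose and 3 fell, 22 when adjusted over the list alone, 17 of them higher (list adjusted p = 0.000775), and Homer1 was up by 0.98. Of 13 NPAS4 targets 7 rose and 1 fell, 10 when adjusted over the list alone, 8 of them higher (list adjusted p = 0.00354). None of the feedback, late-response or NPAS4 target genes fell with the suffix term. Of 23 clock genes 6 rose and 4 fell, 12 when adjusted over the list alone, 7 of them higher (list adjusted p = 0.34). Among 21 SCN peptides and receptors 4 rose and 6 fell, 13 when adjusted over the list alone, 5 of them higher (list adjusted p = 0.486). With the suffix term 2 of this list rose and 1 fell, and Vip, which fell by 0.56 (adjusted p = 0.0354), did not pass (adjusted p = 0.302). Avp (-1.03, adjusted p = 0.122) and Grp (0.04) did not pass. Of 10 oligodendrocyte markers 5 fell, 10 when adjusted over the list alone (list adjusted p = 0.34), and 0 passed with the suffix term.

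At 3 h 1664 genes were called with the label batch, 929 higher and 735 lower, and 471 with the suffix term, 319 higher and 152 lower. The calls in both numbered 383, and the share that were higher was 55.8% and 67.7%. Within label batch 2 alone 2809 were called, and leaving out single libraries gave 291 to 3070. Calls absent with the suffix term included Eomes (adjusted p = 0.13 with it), the globin gene Hbb-bs (0.416), which has a near-identical copy and is uncertain for that reason, and the neuropeptide genes Nts (0.706) and Gal (0.0928). Light of 3 h ended at CT20, for which no dark control is analysed here, so that time of day enters this comparison.

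Light of 6 h was compared with the dark at CT23, its own time of day. The semaphorin gene Sema3e rose by 1.99 ± 0.11, from 21.7 ± 0.237 to 77.1 ± 2.51 CPM (SD, n = 2 each; adjusted p = 5.8e-07), and Vgf by 2.05 ± 0.17, from 149 ± 2.34 to 560 ± 59.4 CPM. Per2 rose by 1.44 ± 0.10, from 45 ± 2.18 to 119 ± 5.16 CPM (adjusted p = 3.58e-06). Prok2 was up by 2.41 ± 0.27 (1.80 with the suffix term), Fbxl21 by 1.84 ± 0.11 and Rora by 1.29 ± 0.13. The oncostatin M receptor gene Osmr rose by 2.77 ± 0.32, the natriuretic peptide receptor gene Npr1 by 2.20 ± 0.28 and Socs3, a suppressor of cytokine signalling, by 1.64 ± 0.21. Lower in light were Ankrd63, by a log2 change of -2.94 ± 0.24, the synaptotagmin gene Syt17 (-1.27 ± 0.18), the deacetylase gene Hdac9 (-0.91 ± 0.10) and Lhx1, a LIM homeobox factor of the SCN (-0.88 ± 0.18).

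At 6 h 2 of 31 immediate-early genes rose, 8 when adjusted over the list alone (list adjusted p = 0.109), Junb among them by 1.43 ± 0.22. Of 24 MAPK and cAMP feedback genes 4 rose, and 14 passed when adjusted over the list alone, 13 of them higher (list adjusted p = 0.000837). Of 23 clock genes 4 rose and none fell, and 6 passed when adjusted over the list alone, 5 of them higher (list adjusted p = 0.0121). Of 29 late-response genes 5 rose, 6 when adjusted over the list alone (list adjusted p = 0.00157), including the prohormone convertase gene Pcsk1 by 0.92 ± 0.15. None of 13 NPAS4 targets passed, 2 when adjusted over the list alone (list adjusted p = 0.755). Among SCN peptides and receptors 2 rose and 1 fell, 5 when adjusted over the list alone, 3 of them higher (list adjusted p = 0.34), and Vip, Avp and Grp did not pass. Npas4 had a log2 difference of -0.48 (adjusted p = 0.423). In all 146 genes differed, 105 higher and 41 lower, and 205 with the suffix term, of which 139 were shared. Per1, which rose by 0.51 ± 0.11 (adjusted p = 0.0371), had an adjusted p of 0.0556 with the suffix term. Each arm has 2 libraries, and without replicate 1 of 6 h 58 genes were called, without replicate 2 of 6 h 87 and without replicate 2 of CT23 552.

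The steps between times were compared directly. From 0.5 h to 1 h Npas4 fell by 2.04 (adjusted p = 2.9e-05), whereas Prok2 rose by 3.56 ± 0.21 (2.51 with the suffix term), Homer1 by 1.91 ± 0.09, the receptor gene Gpr3 by 2.06 ± 0.16 and Fosl2 by 1.65 ± 0.12. Per1 rose by 0.96 ± 0.09 and Per2 by 0.75 ± 0.09. From 1 h to 3 h Egr1 fell, with a log2 change of -3.25, as did Nr4a1 (-3.02), Junb (-2.92), Fos (-2.29, adjusted p = 3.87e-07) and Per1 (-1.12, adjusted p = 1.47e-05). Pde10a rose by 1.22 ± 0.07, the transcription factor gene Bach2 by 1.35 ± 0.15 and the protease gene Adamts9 by 1.64 ± 0.16. Per2 changed by 0.40 ± 0.10 (adjusted p = 0.0648), which passed with the suffix term (adjusted p = 0.0477), and Npas4 by -0.49 (adjusted p = 0.431).

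Between 0.5 h and 1 h 1056 genes differed with the label batch, 588 higher and 468 lower, and 72 with the suffix term, 63 higher and 9 lower, with 69 called in both. The share higher was 55.7% and 87.5%, and leaving out single libraries gave 33 to 2780. Between 1 h and 3 h, whose libraries all belong to label batch 2 without the suffix s, the label batch gave 159 calls and the suffix term 222, of which 158 were shared. Leaving out single libraries gave 69 to 217.

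**Figure D2:**
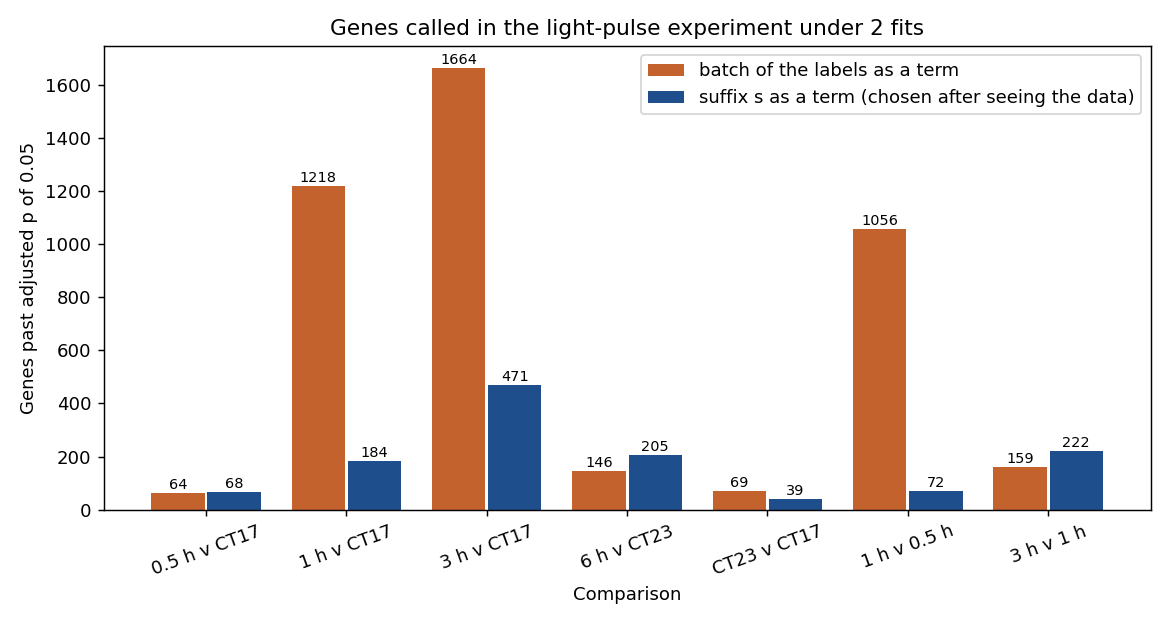
Number of genes called at an adjusted p of 0.05 in the light-pulse comparisons, with orange bars for the model with the label batch and blue bars for the model with the suffix term. At 1 h 1218 genes were called with the label batch, against 184 with the suffix term.

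**Figure D3:**
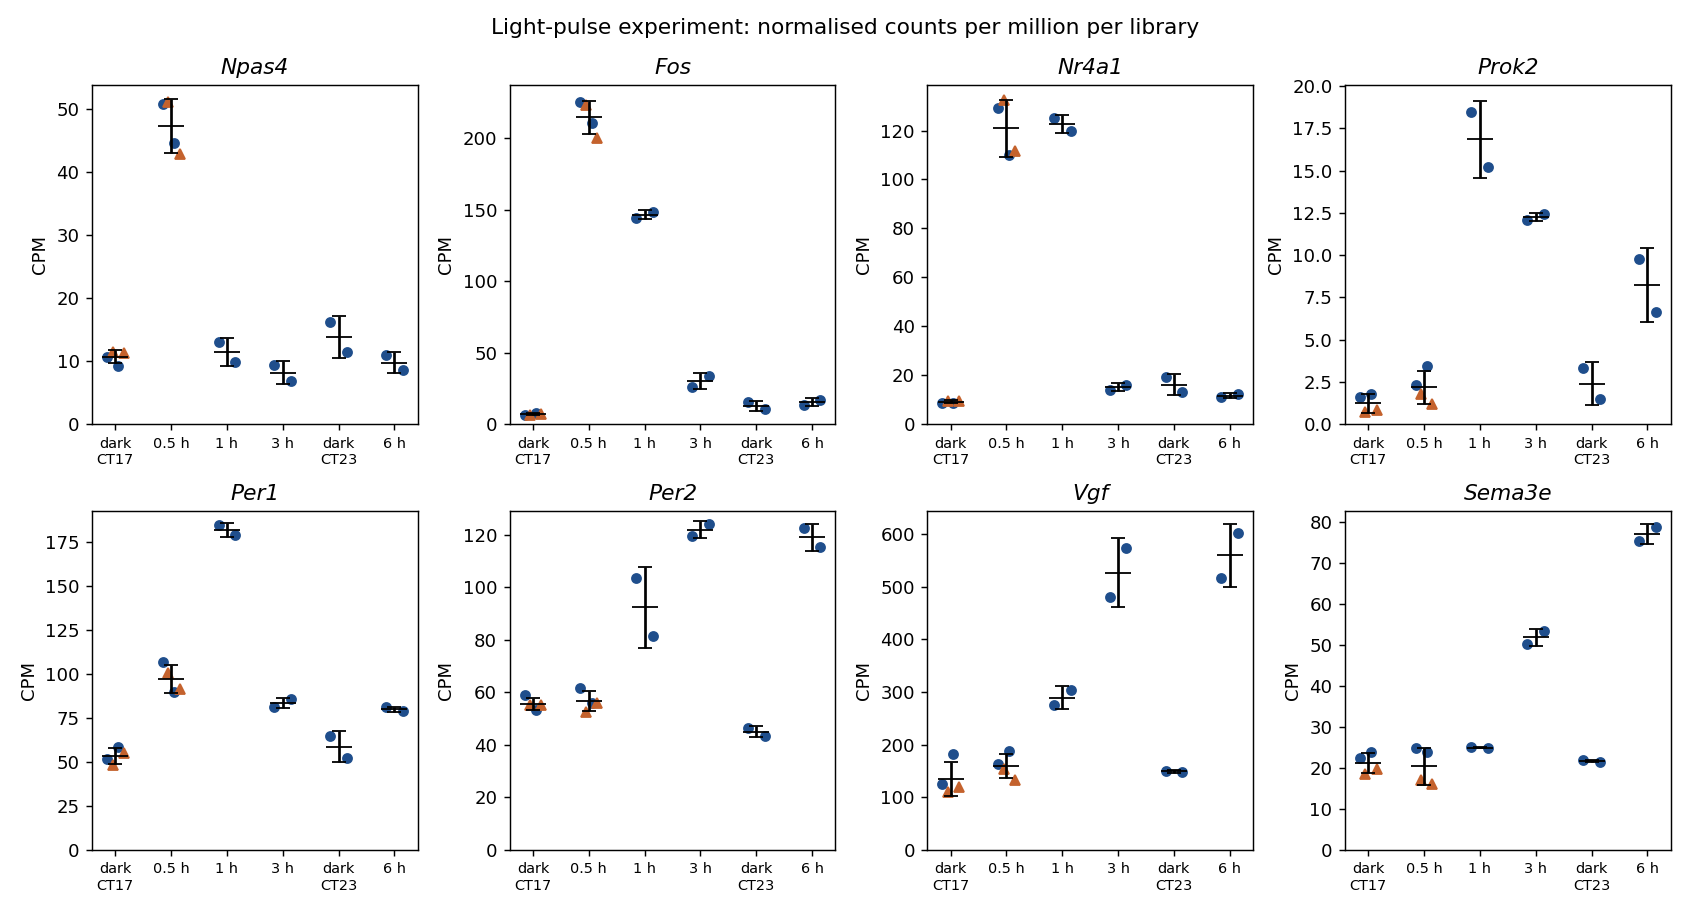
Expression of Npas4, Fos, Nr4a1, Prok2, Per1, Per2, Vgf and Sema3e in CPM (vertical axes from 0) by lighting group, with 1 point per library, orange triangles for the suffix s and bars for mean ± SD. Npas4 is highest at 0.5 h (47.4 CPM), Prok2 at 1 h (16.9 CPM) and Vgf at 6 h (560 CPM).

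In the dark, CT23 was compared with CT17. Rgs16, a regulator of G-protein signalling in the SCN, rose by 1.23 ± 0.09, from 64.2 ± 2.94 (SD, n = 4) to 151 ± 27.8 CPM (n = 2; adjusted p = 1.52e-05). Fabp7, a fatty acid binding protein of glia, rose by 0.96 ± 0.15 and Nr1d1, which encodes REV-ERB alpha, by 0.75 ± 0.12. The glucocorticoid-responsive gene Tsc22d3 fell by 0.83, Sgk1 fell by 1.10, the lipid droplet gene Plin4 fell by 1.27, Rasd1 fell by 0.66 and the clock gene Per3 fell by 0.59. Log2 changes of Per1 (0.13), Per2 (-0.31), Npas4 (0.34) and Vip (-0.56) did not pass.

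Of the immediate-early genes 5 rose at CT23, and 11 passed when adjusted over the list alone, 8 of them higher (list adjusted p = 0.34), and with the suffix term 1 rose. Rises with the label batch included Nr4a1 by 0.79 ± 0.14 and Fos by 0.88 ± 0.16 (adjusted p = 0.0279, and 0.0668 with the suffix term). Of the clock genes 1 rose and 1 fell, 7 when adjusted over the list alone, 2 of them higher (list adjusted p = 0.755). Of the feedback genes 3 rose and 2 fell, 7 when adjusted over the list alone, 5 of them higher (list adjusted p = 0.34). With the suffix term 1 rose and 1 fell, and Dusp4 (0.88 ± 0.17) had an adjusted p of 0.0662 with the suffix term. Of the ER chaperone genes 3 fell, 8 when adjusted over the list alone, with a list adjusted p of 0.109 and 0.0496 with the suffix term and Manf, an ER stress gene, fell by 0.53. In all 69 genes differed, 30 higher and 39 lower, and 39 with the suffix term, of which 35 were shared. The CT23 group has 1 library of each label batch. Within label batch 2 alone 1705 genes were called, without replicate 2 of CT23 8, and without its replicate 1 the count was 1954.

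In the Npas4 experiment the targeted gene was counted first. Npas4 had 146, 281 and 287 reads in the null dark libraries, 127, 236 and 152 in null light, 236, 250 and 249 in wild-type dark and 406, 327 and 423 in wild-type light. In CPM these were 8.60 ± 2.89, 5.79 ± 1.63, 8.39 ± 0.223 and 12.8 ± 1.79 (SD, n = 3). Reads over Npas4 thus remain in the null. Which part of the gene was deleted is not given in the sources used here, so that these counts do not check the genotype labels.

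In wild-type mice 1 h of light raised the AP-1 subunits Fosb by 7.19 ± 0.29 in log2, from 1.24 ± 0.236 to 182 ± 24.5 CPM (SD, n = 3 each; adjusted p = 2.89e-08), and Fos by 5.03 ± 0.20, from 7.99 ± 0.163 to 261 ± 22.6 CPM. Egr1 rose by 6.23 ± 0.35 to 601 ± 29 CPM, and Nr4a1 by 4.55 ± 0.17, from 9.03 ± 1.08 to 213 ± 27.4 CPM. Prok2 rose by 4.41 ± 0.41, from 0.643 ± 0.14 to 13.7 ± 4.65 CPM. Per1 rose by 2.16 ± 0.11, from 48.6 ± 1.67 to 218 ± 4.88 CPM, and Per2 by 1.29 ± 0.09, from 52.1 ± 0.769 to 127 ± 16.2 CPM (adjusted p = 2.78e-06). Npas4 had a log2 change of 0.61 ± 0.23 (adjusted p = 0.34). Npy6r fell by 1.31 (adjusted p = 0.00598) and the Notch target Hes5 fell by 1.29 (adjusted p = 0.00165).

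Of 31 immediate-early genes 26 rose, 28 when adjusted over the list alone (list adjusted p = 5.46e-05). Of 25 MAPK and cAMP feedback genes 14 rose, and 18 passed when adjusted over the list alone, 17 of them higher (list adjusted p = 7.42e-05), with Rrad up by 4.76 ± 0.21 and Gem by 2.66 ± 0.16. Of 29 late-response genes 16 rose, 17 when adjusted over the list alone (list adjusted p = 7.36e-05), with Homer1 up by 3.05 ± 0.16 and Vgf by 1.30 ± 0.14. Of 13 NPAS4 targets 6 rose, 7 when adjusted over the list alone (list adjusted p = 4.59e-05). Of 23 clock genes 4 rose, and 6 passed when adjusted over the list alone, 5 of them higher (list adjusted p = 0.087). Of 22 SCN peptides and receptors 2 rose, 2 when adjusted over the list alone (list adjusted p = 0.11). Vip (-0.20), Avp (0.71) and Grp (0.02) did not pass. In all 386 genes differed, 335 higher and 51 lower. With the replicate number as a block 755 differed, 555 higher and 200 lower, so that the share higher was 86.8% without and 73.5% with the block.

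In Npas4 null mice light raised Fosb by 5.28 ± 0.25, Egr1 by 4.69 ± 0.33 and Fos by 3.15 ± 0.18, from 21.7 ± 3.49 to 192 ± 50.5 CPM (SD, n = 3 each; adjusted p = 9.42e-07). Nr4a1 rose by 2.86 ± 0.15, from 21.8 ± 1.79 to 158 ± 31.9 CPM, Prok2 by 2.54 ± 0.29 and Homer1 by 2.5 ± 0.16. Per1 rose by 1.74 ± 0.11, from 64 ± 3.84 to 213 ± 40 CPM, and Per2 by 0.64 ± 0.09, from 72.5 ± 7.38 to 113 ± 5.24 CPM (adjusted p = 0.0016). Of 31 immediate-early genes 25 rose, and 28 passed when adjusted over the list alone, 27 of them higher. Of 25 feedback genes 13 rose, 16 when adjusted over the list alone. Of 29 late-response genes 12 rose, 16 when adjusted over the list alone, of 13 NPAS4 targets 6, 7 when adjusted over the list alone, and of 23 clock genes 3, with 6 past when adjusted over the list alone, 5 of them higher. Their list adjusted p-values were 7.42e-05, 0.000168, 0.000183, 5.46e-05 and 0.0995 in the same order. Among the SCN peptides and receptors 2 rose, 2 when adjusted over the list alone (list adjusted p = 0.286). Npas4 had a log2 change of -0.57 ± 0.24 (adjusted p = 0.557). In all 234 genes differed, 217 higher and 17 lower, including the protease gene Adamts15, which fell by 0.92. With the replicate block 452 differed, 383 higher and 69 lower. Without replicate 2 of null light 155 were called. None of 8 meningeal fibroblast markers passed, but 6 were lower in null light when adjusted over the list alone, with a list median of -1.19 and a list adjusted p of 0.33.

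The difference between these responses was tested as an interaction. The 2 genes past the threshold were Fos and Nr4a1, with smaller rises in the null, by a log2 difference of -1.88 ± 0.25 (adjusted p = 0.0453) and -1.70 ± 0.21 (adjusted p = 0.0445). In the dark both genes were higher in the null, by 1.44 and 1.27, past the threshold. After light they differed from wild type by -0.44 and -0.43, which did not pass. Of 31 immediate-early genes these 2 had a smaller rise, and 18 when adjusted over the list alone, with a list median of -0.772 and a list adjusted p of 0.0039. For the feedback genes none passed, 2 when adjusted over the list alone (list adjusted p = 0.0132), and the list call was lost with the replicate block (adjusted p = 0.0908). For the late-response genes none passed, 3 when adjusted over the list alone, with a median of -0.388 and a list adjusted p of 0.0039. For the NPAS4 targets 1 passed, 1 when adjusted over the list alone (list adjusted p = 0.00145). It is Nr4a1, already counted among the immediate-early genes. Most NPAS4 targets are members of other lists tested here, so this p-value is not separate evidence. For the clock genes none passed, 1 when adjusted over the list alone (list adjusted p = 0.742), and none of the SCN peptides did. Per2 (-0.64 ± 0.13, adjusted p = 0.793), Dusp4 (-1.29 ± 0.21, adjusted p = 0.201), Fosl2 (-1.37 ± 0.29), Prok2 (-1.87 ± 0.54), Homer1 (-0.56), Per1 (-0.43) and Npas4 (-1.18) did not pass. None of 8 meningeal fibroblast or 14 neighbouring hypothalamic neuron markers passed either, with list medians of -1.12 (list adjusted p = 0.239) and -0.377 (list adjusted p = 0.47).

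In all 342 genes had an unadjusted interaction p under 0.05, fewer than the 750 expected by chance among 15001 genes with no change. With RLE scaling the adjusted p was 0.0503 for Fos and 0.0495 for Nr4a1, with limma 0.0711 for both, and 9 of the 12 libraries each ended both calls when left out, all but replicate 1 of null dark and replicates 1 and 2 of null light.

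The genes induced at 1 h in the other experiment by a log2 change of 1 or more were tested as a list. Of these 94 genes 73 had an interaction below 0 (77.7%), with a median of -0.328 (limma fry, adjusted p = 0.00942 over 4 such lists). For the 32 genes induced at 0.5 h the median was -0.987 and 30 lay below 0 (adjusted p = 0.00942), and for the 59 genes from the suffix term it was -0.686 with 57 below 0 (adjusted p = 0.00942). For 302 genes with a rise of 0.5 or more the median was -0.072 (adjusted p = 0.0657). A negative interaction can come from a higher level in the dark or a lower level in light. For 60 genes induced at 0.5 h or 1 h under both fits, mean log2 CPM was 2.93 to 3.13 in null dark and 2.48 to 2.56 in wild-type dark. In light the libraries overlapped, at 4.77 to 5.32 in the null and 5.20 to 5.48 in wild type. The list result thus does not by itself show weaker induction.

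In the dark, null mice were compared with wild-type littermates. Cck, which encodes cholecystokinin, was lower in the null at 5.88 ± 1.02 against 41.1 ± 4.66 CPM (SD, n = 3 each), a log2 change of -2.80 ± 0.17 (adjusted p = 8.09e-06). The axon guidance receptor gene Robo3 was lower by a change of -4.36 ± 0.26, at 0.373 ± 0.0908 against 7.75 ± 1.91 CPM. The cadherin gene Dchs2 (-1.27 ± 0.17), the dopamine receptor gene Drd5 (-1.16 ± 0.17), the dopamine transporter gene Slc6a3 (-1.0 ± 0.17) and Abcc8, a subunit of ATP-sensitive potassium channels (-0.91 ± 0.09), were lower too. Prok2 was higher by 3.34 ± 0.44, at 6.53 ± 2.33 against 0.643 ± 0.14 CPM (adjusted p = 0.00292), and Rgs16 by 1.84 ± 0.16, at 351 ± 80.7 against 98.3 ± 6.01 CPM. The neuromedin genes Nms and Nmu were higher by 1.47 ± 0.20 and 2.54 ± 0.32, Vgf by 0.95 ± 0.14, the cytokine gene Clcf1 by 2.40 ± 0.21 and the neurotrophin gene Bdnf by 1.01 ± 0.08.

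Of the immediate-early genes 4 were higher in the null in the dark, 13 when adjusted over the list alone (list adjusted p = 0.0952), with Fos up by 1.44 ± 0.19 and Nr4a1 by 1.27 ± 0.16. Of the feedback genes 4 were higher, 9 when adjusted over the list alone (list adjusted p = 0.0116), with Dusp4 up by 1.35 ± 0.16. Of 13 NPAS4 targets 2 were higher, 5 when adjusted over the list alone (list adjusted p = 0.00304), and of the late-response genes 2, 4 when adjusted over the list alone (list adjusted p = 0.092). Of 22 SCN peptides and receptors 4 were higher and 1 lower, 8 when adjusted over the list alone, 6 of them higher (list adjusted p = 0.024). With the block the list calls of the feedback genes (adjusted p = 0.0945), the NPAS4 targets (0.0697) and the SCN peptides and receptors (0.0851) were lost. None of 8 meningeal fibroblast markers passed, 2 were higher when adjusted over the list alone, and the list median was 0.901 (list adjusted p = 0.467). Of 23 clock genes 1 was higher and 1 lower, Per2 (0.48 ± 0.09, adjusted p = 0.0317) and Per3 (-0.38 ± 0.07), and 7 passed when adjusted over the list alone, 4 of them higher (list adjusted p = 0.734). Per1 (0.40, adjusted p = 0.183), Vip (0.44) and Npas4 (0.04, adjusted p = 0.989) did not pass, nor did Avp (1.14 ± 0.34, adjusted p = 0.243), which passed with the block (adjusted p = 0.0239). In all 113 genes differed, 65 higher and 48 lower, and 463 with the block, 252 higher and 211 lower. Without replicate 3 of wild-type dark 48 were called, without replicate 2 of wild-type dark 60 and without replicate 3 of null dark 70.

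After 1 h of light, Cck (-2.75 ± 0.17, 5.49 ± 0.995 against 37.2 ± 6.86 CPM; SD, n = 3 each) and Robo3 (-4.56 ± 0.27) were again lower in the null, with adjusted p-values of 1.01e-05 and 8.98e-06, as were Dchs2 (-1.16 ± 0.17) and Drd5 (-0.97 ± 0.17). In all 23 genes were lower in the null in the dark and in light. Clcf1 was higher by 2.24 ± 0.20, Nmu by 3.06 ± 0.36, Nms by 1.49 ± 0.20, Bdnf by 0.98 ± 0.08, the phosphatase inhibitor gene Ppp1r1a by 1.52 ± 0.15 and Prok2 by 1.48 ± 0.27, at 37.9 ± 9.39 against 13.7 ± 4.65 CPM (adjusted p = 0.0333). Npas4 differed by -1.14 ± 0.24 (adjusted p = 0.0663). Fos (-0.44, adjusted p = 0.573), Nr4a1 (-0.43, adjusted p = 0.393), Per1 (-0.03), Per2 (-0.17) and Vip (0.74, adjusted p = 0.359) did not pass.

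Of the immediate-early genes 1 was lower in null light, and 8 passed when adjusted over the list alone, 1 of them higher (list adjusted p = 0.239). Of the SCN peptides and receptors 3 were higher and 1 lower, 6 when adjusted over the list alone, 5 of them higher (list adjusted p = 0.102). Of the late-response genes 1 was higher, and 12 passed when adjusted over the list alone, 2 higher and 10 lower, with a list median of -0.131 (list adjusted p = 0.186). Of the feedback genes 1 was higher, and 3 passed when adjusted over the list alone, 2 of them higher (list adjusted p = 0.813), and of the clock genes 1, with 3 past when adjusted over the list alone, 2 of them higher (list adjusted p = 0.986). Among NPAS4 targets 1 was higher, 1 when adjusted over the list alone (list adjusted p = 0.986). In all 70 genes differed, 41 higher and 29 lower. Leaving out any 1 of the 6 light libraries left 32 to 42.

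**Figure D4:**
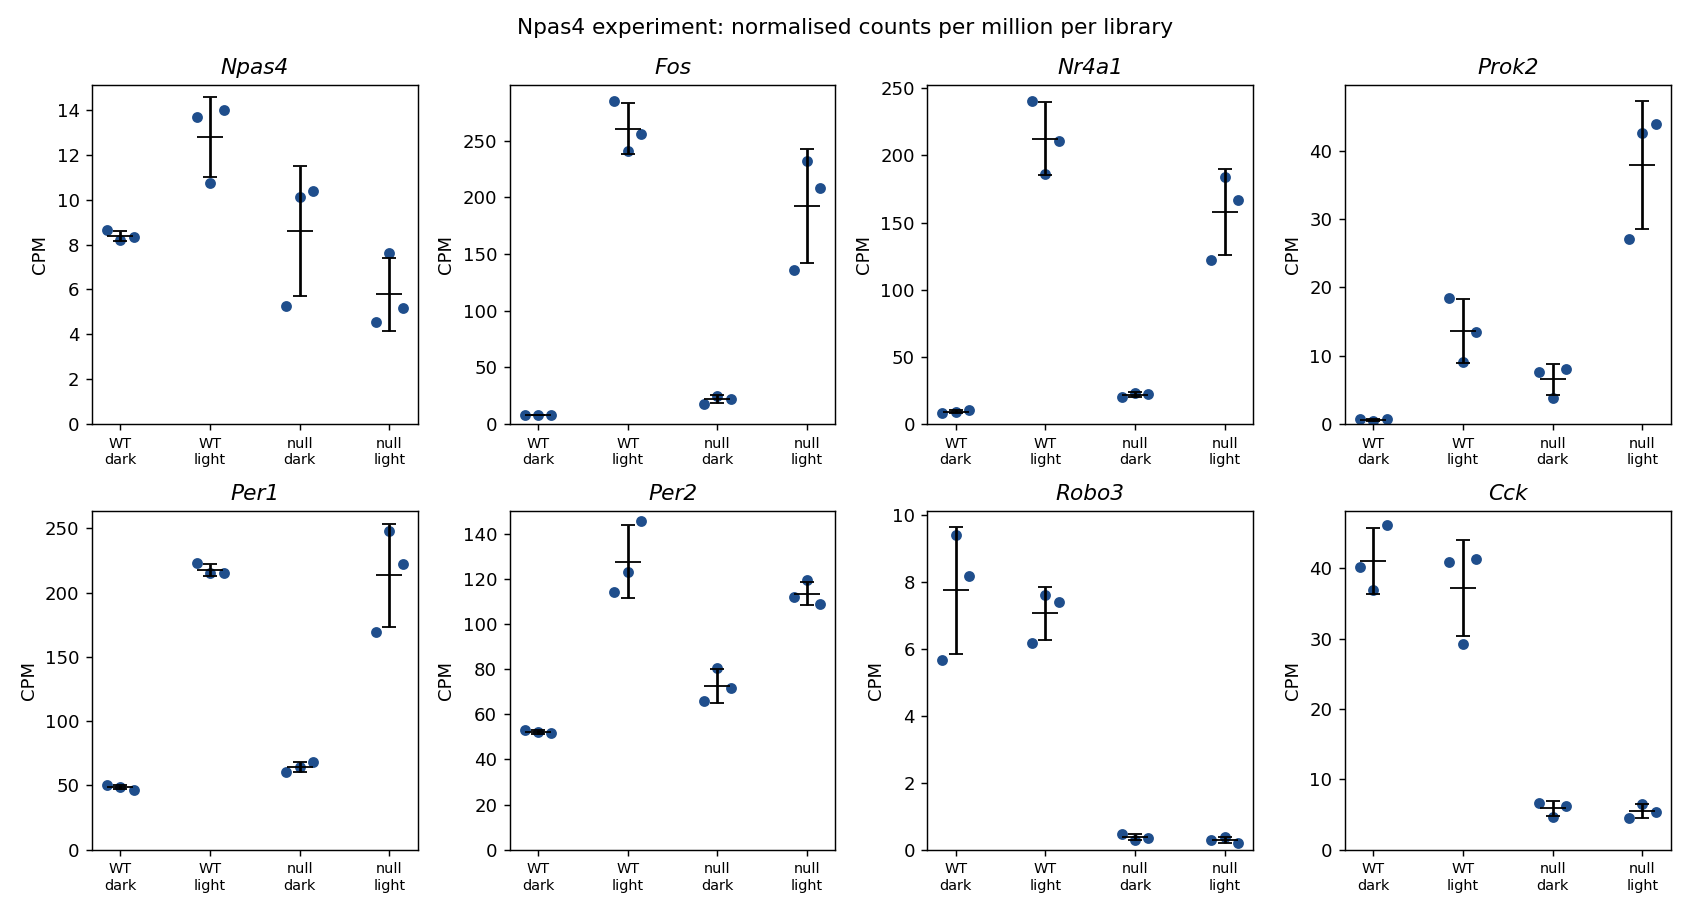
Expression of Npas4, Fos, Nr4a1, Prok2, Per1, Per2, Robo3 and Cck in CPM (vertical axes from 0) in wild-type and Npas4 null mice in dark and light, with 1 point per library and bars for mean ± SD of 3 libraries. Cck lies near 5.88 CPM in null dark against 41.1 CPM in wild-type dark, and Fos rises with light in both genotypes.

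The 1 h response was measured in both experiments, with separate controls. Across 14476 genes, which are not independent replicates, the log2 changes correlated with a Pearson r of 0.407 and a Spearman rho of 0.112. The rho was 0.00129 without replicate 3 of wild-type dark, 0.0639 without its replicate 1, 0.231 without its replicate 2 and 0.0414 without replicate 2 of wild-type light. Of 1215 genes called at 1 h 717 had the same sign in wild-type mice of the Npas4 experiment (59.0%), 70.0% of the rises and 47.0% of the falls. With the suffix term r was 0.537 and 176 of 184 calls had the same sign (95.7%), all rises (100%) and 65.2% of the falls.

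ChIP-seq asked where histone marks differ between dark and light. The authors' list of H3K27ac held 40403 peaks in light and 38447 in dark, and 65.1% of the light peaks and 67.4% of the dark peaks overlapped a peak of the other. H3K4me3 had 27551 peaks in light and 30410 in dark, with 95.8% and 76.3% overlapping. At Fos (mm10, chromosome 12, 85473890 to 85477274) 7 H3K27ac peaks lay within 2 kb of a gene end in light and 3 in dark. At Fosl2 (chromosome 5, 32136472 to 32157840) there were 5 and 2, at Per1 (chromosome 11, 69095108 to 69109965) 2 and 4, at Nr4a1 (chromosome 15, 101253902 to 101274795) 0 and 2, and at Npas4 (chromosome 19, 4984353 to 5003439) 2 and 2. A count depends on how the signal was divided into peaks. The authors' fold enrichment of the peak with the highest -log10 q-value did not follow the count at each gene. It was 7.44 in light and 9.14 in dark at Fos, 8.20 and 7.38 at Fosl2, 13.4 and 12.0 at Per1, 6.82 and 9.52 at Npas4, and 6.16 in dark at Nr4a1. These values come from separate lists without replicates, so no change can be read from them or from the counts.

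Of 637 genes higher at 1 h that have a position, 261 (41.0%) had an H3K27ac peak of light alone within 10 kb of a gene end, against 4838 of 13795 other genes (35.1%), an odds ratio of 1.28 (two-sided Fisher exact p = 0.002596). For peaks of dark alone the shares were 29.4% and 35.2%, with an odds ratio of 0.764 (two-sided Fisher exact p = 0.002207). For these the odds ratio was 0.674 (exact p = 0.0001845) within 2 kb, 0.718 (exact p = 5.49e-05) within 50 kb and 0.713 (exact p = 0.000336) against matched genes, but 0.937 (exact p = 0.512) among peaks with a -log10 q of 10 or more, 0.788 (exact p = 0.184) for genes called higher with the suffix term and 0.803 (exact p = 0.184) for genes induced in both experiments. Against genes matched on mean expression the odds ratio of light-alone peaks was 1.12 (exact p = 0.213), and within 50 kb it was 0.960 (exact p = 0.646). Within 2 kb it was 1.29 (exact p = 0.00586), and among peaks with a -log10 q of 10 or more 1.37 (exact p = 0.00575). For the 161 genes called higher with the suffix term the odds ratio of light-alone peaks was 2.17 (87 genes, exact p = 1.18e-06), and against matched genes 1.85 (exact p = 0.000441). For genes induced in both experiments 100 of 182 had such a peak, an odds ratio of 2.26 (exact p = 7.44e-08).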

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

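The libraries and the difference between genotypes given here were found by fixed rules, and of the tests of explanations only that of light or activity before collection was chosen after its result was seen. The splits within replicate numbers were added late, but before their own result was seen.

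In the light-pulse groups with 4 libraries, single libraries stood far from the others of their group in 6 of 106 tests, of 53 named genes in 2 groups each, and chance marks about 1 in 20. Avp lay at 119 CPM in replicate 2s of dark CT17, against 74.8 to 81.3 in the others. Plk2 lay at 26.8 CPM in replicate 1 of dark CT17, against 29.4 to 29.7. In replicate 2 of light 0.5 h Cnn1, a smooth muscle calponin, lay at 5.33 CPM against 0.563 to 0.838, and Npy6r at 9.96 CPM against 14.1 to 14.6. In replicate 1 of light 0.5 h Rora lay at 126 CPM against 94 to 98.7, and Sgk1 at 36.5 CPM against 56.4 to 59.7.

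The light responses of Fos and Nr4a1 differed between genotypes, with interaction terms of -1.88 and -1.70 in log2. Both genes were higher in the null in the dark (by 1.44 and 1.27), and neither difference passed in light (-0.44 and -0.43). Over 19 other settings the term lay between -2.04 and -1.68 for Fos, with adjusted p-values from 3.7e-10 to 0.268 and 8 settings past the threshold, and between -1.82 and -1.52 for Nr4a1, from 1.03e-10 to 0.227 with 9 past. Of 100 splits of the 12 libraries 2 gave as many genes as the real 2, with 5 as the highest other value. Since most same-number libraries correlate, genotype was also swapped only within a number and lighting. Of these 32 splits 4 gave as many genes, with 289 as the highest other where all light libraries were swapped, which adds the genotype differences in dark and light in place of comparing them. Without that split 3 remain, so that chance is not excluded for the count. For the median of genes induced at 1 h, 3 of 100 splits gave a size as large as the real 0.328, with 0.405 as the highest other. Of the 32 splits within numbers only the real 1 did, with 0.317 as the highest other. Both shares lay under 0.05, but the margin within numbers was narrow. Between null and wild type in light the lowest same-number correlation was 0.0197. The 302 genes with a rise of 0.5 or more did not pass as a list (limma fry, adjusted p = 0.0657).

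In the dark 4 of 31 immediate-early genes, Fos and Nr4a1 among them, were higher in the null (list adjusted p = 0.0952). Differing amounts of tissue next to the SCN were argued against only as far as the mean of the meningeal and neighbouring neuron markers follows them. With this mean as a covariate 96.9% of the genes higher in the null kept their call. The kinds of marker were not corrected for separately, so tissues that vary apart are not covered. A later circadian phase stays open. The 30 genes that rose from CT17 to CT23 had a median of 0.316 in the null (adjusted p = 0.00396, limma fry). They include Fos, Nr4a1, Dusp4 and Rgs16, which are among the genes higher in the null, so this value in part restates the pattern. The 39 that fell had a median of -0.0290 (adjusted p = 0.109, limma fry), so that the test did not decide. Light or activity before collection stays open too. The mean log2 CPM of genes induced by 0.5 h or 1 h of light was above every wild-type dark library in 3 of 3 null dark libraries (2.93, 3.04 and 3.13 against 2.48, 2.51 and 2.56), but this restates the pattern and cannot be told apart from an effect of the loss of Npas4 itself, which the design names and which was not tested.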

How the results depend on the processing

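The terms for the suffix s, the sets without the libraries that carry it, the splits balanced for it and the comparisons of 1 h with 0.5 h and 3 h with 1 h were chosen only after the results were seen. Over all settings, named genes kept their side of the threshold in 5265 cases, gained a call in 43 and lost one in 184. Where a gene passed in the main fit or in the other setting, its direction reversed in 0 cases. Changes of direction where it passed in neither were not counted. For the changes of counts given here the cause was not tested, except that a stricter fold threshold, fewer libraries or another control change the question by construction.

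With an absolute log2 change of 1 or more required, calls numbered 32 at 0.5 h, 176 at 1 h, 179 at 3 h, 48 at 6 h, 11 for CT23, 145 for 1 h against 0.5 h, 47 for 3 h against 1 h, 113 for light in wild type, 67 for light in the null, 40 for genotype in the dark and 26 in light. DESeq2 called 238 at 6 h, 268 for CT23, 257 for genotype in the dark, 163 in light and 11 for the interaction, where RLE scaling called 1 and limma 0 (342 genes had an unadjusted edgeR p under 0.05, against 750 expected with no change). Fits on only the groups compared called 141 for light in the null, 35 for genotype in the dark and 119 in light.

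In the light-pulse experiment the counts at 1 h, 3 h, CT23 and 1 h against 0.5 h differed with the batch term and the libraries used. They were 184, 471, 39 and 72 with the suffix term, 182, 462, 43 and 71 with no batch term, 119, 197, 3 and 37 without the 4 libraries with the suffix s, and 2494, 2809, 1705 and 3165 in label batch 2 alone. With libraries of a number summed and no batch term they were 880, 1354, 341 and 825. The 6 h light group against dark CT17 gave 1896 calls, and 3 h against the mean of both dark groups 780.

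With the replicate number as a block, light-pulse calls numbered 2209 at 1 h, 2696 at 3 h, 226 at 6 h, 141 for CT23 and 2318 for 1 h against 0.5 h, but there only 32 of 52 same-number pairs correlated above 0.1 and the numbers do not pair the libraries. In the Npas4 experiment the block gave 755 calls for light in wild type, 452 in the null, 463 for genotype in the dark and 227 in light, and the interaction kept 2 (adjusted p = 0.0263 for both). The list calls of the feedback genes, NPAS4 targets and SCN peptides in the dark were lost (adjusted p = 0.0945, 0.0697 and 0.0851), as was that of the feedback genes for the interaction (0.0908). In the dark it added Avp. In light, where 2 of 3 same-number pairs exceeded 0.1 (lowest correlation 0.0197), it added Npas4 (adjusted p = 0.0171) and Vip (adjusted p = 0.0351). It changed no other call of a named gene or list in that experiment.

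Leaving out single libraries gave 172 to 2698 calls at 1 h, with 172 and 506 without replicates 1 and 2 of 1 h, 497 without either dark CT17 library with suffix s, and 2698 and 2687 without replicates 1 and 2 of CT23. At 3 h it gave 291 to 3070, with 756 and 291 without replicates 1 and 2 of 3 h, 655 and 775 without CT17 1s and 2s, and 3070 and 3065 without CT23 1 and 2. At 6 h it gave 58 to 552, with 58 and 87 without 6 h 1 and 2 and 552 without CT23 2. For CT23 it gave 8 to 1954, with 1954 and 8 without CT23 1 and 2, 42, 27 and 33 without CT17 1, 1s and 2s, and 43 without 1 h 1. For 1 h against 0.5 h it gave 33 to 2780, with 33 and 206 without 1 h 1 and 2, 274, 1596 and 119 without 0.5 h 1s, 2 and 2s, 647 and 687 without CT17 1s and 2s, and 2780 and 2768 without CT23 1 and 2. For 3 h against 1 h it gave 69 to 217, with 69 and 75 without 1 h 1 and 2, and 83 and 81 without 3 h 1 and 2. Where a group of 2 lost a library, the remaining one was assumed to vary like the other groups.

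In the Npas4 experiment genotype in light ranged from 32 to 81, with 38, 37 and 32 without wild-type light 1, 2 and 3 and 42, 35 and 33 without null light 1, 2 and 3. Genotype in the dark ranged from 48 to 104, with 60 and 48 without wild-type dark 2 and 3 and 70 without null dark 3. Light in the null ranged from 155 (without null light 2) to 249. The interaction ranged from 0 to 3, with 0 without null dark 2 or 3, null light 3 or any wild-type library. Within 1.5 times stayed 0.5 h (56 to 70), light in wild type (262 to 413), the list tests (40 to 50 and 35 to 47), the Pearson correlation of both experiments (0.338 to 0.435) and the interaction median of genes induced at 1 h (-0.389 to -0.241). The Spearman rho of both experiments ranged from 0.00129 to 0.231, without wild-type dark 3 and 2.

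Of the list tests 16 passed with an estimated correlation and 26 with fry in the light-pulse experiment, and 15 and 19 in the Npas4 experiment. The interaction median was -0.072 for genes induced by 0.5 or more. The Pearson correlation of both experiments was 0.560 for genes of at least 5 CPM, 0.598 on RPKM and 0.537 with the suffix term. Of light H3K27ac peaks 37.65% overlapped reciprocally over 0.5 of their length, 72.98% at a -log10 q of 10 or more and 66.81% with equal numbers, and of H3K4me3 peaks 71.55%, 98.51% and 94.41%. The odds ratio of light-alone peaks near induced genes was 0.960 within 50 kb (two-sided Fisher exact p = 0.646) and 1.12 against matched genes (two-sided Fisher exact p = 0.213).

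At 0.5 h 4 of 35 splits gave as many calls as the real split (64, highest other 396), so that this count of splits does not exclude chance by itself. The split with 396 parts libraries without the suffix s from those with it, which points to a structure of the samples. Of the 18 splits with equal numbers of them in each group only the real 1 gave as many, with 0 as the highest other, but 18 are too few for a share under 0.05. Label batch 2 alone gave 56 calls, and single changes such as that of Fos, from 6.83 ± 0.856 to 215 ± 11.5 CPM (SD, n = 4 each), lay far beyond the spread between libraries. For light in wild type (real 386), light in the null (234), genotype in the dark (113) and in light (70) the 10 splits each are too few for a share under 0.05, with only the real 1 as large and 0 as the highest other. With 2 libraries in most light-pulse groups and totals of 12477382 reads upward, simulated 2-fold changes at 1 h were recovered at 93.3%. Recovery of smaller changes and of rare transcripts was not measured, and such changes may be missed.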

Other observations

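All tests of explanations in this part other than the correction of the lower genes for tissue markers were chosen only after the results were seen.

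None of 20 GABA synapse, 16 glutamate receptor or 27 ion channel genes passed at 0.5 h, 6 h or for light in the null, and 1 GABA synapse gene rose at 6 h with the suffix term. At 1 h 4 GABA synapse genes rose and 1 fell (list adjusted p = 0.685), 1 glutamate receptor gene rose (list adjusted p = 0.585), and 1 ion channel gene rose and 3 fell (list adjusted p = 0.845), and no gene of these lists passed with the suffix term. At 3 h 4 GABA synapse genes rose (list adjusted p = 0.717), 5 glutamate receptor genes rose (list adjusted p = 0.486), and 2 ion channel genes rose and 4 fell (list adjusted p = 0.998). With the suffix term 1 GABA synapse gene rose at 3 h and none of the glutamate receptor or ion channel genes passed. Of 10 SCN identity transcription factors 1 rose and 1 fell at 1 h (list adjusted p = 0.871), 2 rose and 2 fell at 3 h (list adjusted p = 0.598), and 1 rose and 1 fell at 6 h, Rora and Lhx1 (list adjusted p = 0.486). The counts with the suffix term were 1 and 0, 2 and 1, and 1 and 1. In wild-type light 1 rose. Of 14 cytosolic heat shock genes 2 rose with light in wild type (list adjusted p = 0.33) and 2 in the null (list adjusted p = 0.239). Of 3 cold-inducible RNA-binding genes 1 rose and 1 fell in wild-type light (list adjusted p = 0.817), 1 rose in the null (list adjusted p = 0.467) and 1 rose at 1 h (list adjusted p = 0.486), with none at 1 h under the suffix term. At 3 h 5 cholesterol synthesis genes rose and 1 fell (list adjusted p = 0.486), none with the suffix term, and 4 ER chaperone genes fell (list adjusted p = 0.62), 2 with it.

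Markers of other cell types were measured too. Of 10 astrocyte markers 1 rose and 2 fell at 1 h and 2 fell at 3 h, of 10 microglia markers 3 fell at 1 h and 3 at 3 h, and of 12 endothelial and mural markers 1 fell at each of these times. No marker of these 3 lists passed at 1 h with the suffix term, whereas at 3 h 1 astrocyte and 1 microglia marker still fell. At 6 h none passed, and 1 astrocyte marker rose with the suffix term. None of 8 meningeal fibroblast markers or of the choroid plexus markers passed in any of the 10 comparisons tested with lists, and with the replicate block 1 meningeal marker fell with light in the null and 1 choroid plexus marker was lower in the null in the dark. Of 14 neighbouring hypothalamic neuron markers 2 rose and 2 fell at 1 h (list adjusted p = 0.595) and at 3 h (list adjusted p = 0.798), and 0 passed with the suffix term at either time. Of 9 ependymal and tanycyte markers 2 rose and 1 fell at 1 h (list adjusted p = 0.599), 0 with the suffix term, and 1 rose and 1 fell at 3 h (list adjusted p = 0.741), with 1 and 0 under it. At 6 h their list adjusted p was 0.0483 (0.181 with the suffix term), with none past over all genes and 2 higher when adjusted over the list alone. Dio2, the deiodinase gene of tanycytes, rose by 1.13 ± 0.13 with light in wild type (adjusted p = 0.000141).

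The calls at 1 h and 3 h of light depended on the batch term. Whether the batch of the labels follows how the libraries differ was examined on the first principal component. There 7 of the 7 libraries of label batch 2 without the suffix s lay nearer the mean of label batch 1 than that of the libraries with it, but these scores had prompted the suffix term. The 7 (-16.2 to -6.13) barely overlapped label batch 1 (-6.61 to 8.64), and the libraries with the suffix s lay at the other end (15.4 to 25.2). Label batch 2 thus held both ends of this component, which argues against the label batch following it. Label batch 1 has no library of 1 h, 3 h or 6 h, so the lighting time differs too. For other differences between the libraries the question stays open. Meningeal tissue in the libraries with the suffix s was argued against, since the highest change of a meningeal marker between them and the others of their groups was 0.270 in log2. Neighbouring hypothalamic tissue could not be decided, since its markers went both ways, with the lowest at -1.53. Depth, which differs with the suffix s, cannot be told apart from it, and no biological explanation was tested for this pattern.

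In all 23 genes, Cck and Robo3 among them, were lower in the null in the dark and in light. A strain segment carried along with the Npas4 locus and holding these genes was argued against for the set, since 21 of the 23 lay on other chromosomes than Npas4. Gene positions cannot show whether such a segment changes genes elsewhere, so that is not covered. For Lrrc10b (10455371 to 10457447) and A1cf (31868756 to 31952365), which lie on chromosome 19 with Npas4 and were named after their values were seen, such a segment stays open. The enrichment of called genes within 10 Mb of Npas4 (odds ratio 1.03, two-sided Fisher exact p = 0.721) did not decide. Tissue next to the SCN was argued against only as far as the marker mean follows it, since 100% of the genes kept both calls with this mean as a covariate. Tissues that vary apart are not covered by it. A dependence of these genes on Npas4 remains a hypothesis that this design cannot separate from other differences between the null and wild-type mice.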
